A study of Mus musculus with 12 samples.

How the data were processed

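Open chromatin was profiled by Omni-ATAC-seq, a version of the assay for transposase-accessible chromatin in which Tn5 transposase cuts and tags accessible DNA. The material was intestinal epithelium of C57BL/6 mice that carry a Sox9-EGFP reporter. The labels name 4 sorted populations by reporter level, Sox9 Negative, Sublow, Low and High, with 3 libraries each (12 libraries, replicates A to C). The label of every library gives 12000 cells collected per population, and does not say whether this number is for each library. The labels do not say whether the libraries of a population came from separate animals.

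Per the submitters' processing notes, the tools used were Trim Galore 0.4.3, Bowtie2 2.3.4, Picard 2.10.3, deepTools 2.5.2 and MACS2 2.1.2, with the mm9 build. The notes used here give no role, order or setting for them, and whether cut positions were shifted for the Tn5 offset is not given in the sources used here. The authors deposited 1 consensus peak list per population, and these 4 lists are the data analysed here. Each list holds a chromosome, a start, an end and a peak name. The lists hold no score, height, read count or value per library, and the rule by which the libraries were combined is not given in the sources used here. Sequencing depth is therefore unknown, and no value in the report has a replicate error.

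Several properties were checked on the lists. Peak names ran without a gap from 1 to the last peak, and no peaks of one list overlapped (smallest gap 130 bp in Negative, 150 bp in Sublow, 148 bp in Low and 131 bp in High). In every list at least 1 peak had a start equal to its end, so positions were taken as counted from 1 with the end included, and widths as end minus start plus 1. Starts would be off by 1 bp if those peaks were errors. Widths reached down to 1 bp in each list. The last peak on chromosome 1 ended at 197068041 in the Negative list, beyond the last chromosome 1 gene of the GRCm38 gene table at hand. A peak can lie past the last gene, so this alone does not exclude GRCm38. The build was taken from the submitters' notes, and mm9 positions are given throughout. An mm9 genome or annotation was not used here. No peak was therefore assigned to a gene, promoter, exon or motif, and the gene lists and motif list fixed beforehand were not used.

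Peaks of the 4 lists that overlapped by at least 1 bp, or touched, were merged, and each merged region was described by which lists held a peak in it. A region held by only 1 list is called an own region of that population. Absence from a list means that no consensus peak was listed there, not that the DNA was closed. Overlap of 2 lists was measured as the Jaccard index over bases, the bases covered by both lists divided by the bases covered by either. Intervals of 95% came from 1000 bootstrap draws of 5 Mb blocks of the genome, and shares also have exact (Clopper-Pearson) binomial intervals. The exact intervals cover counting error only and treat regions or peaks as independent. The bootstrap intervals also cover variation along the genome. Neither kind covers differences between animals or libraries. The background overlap of unrelated lists was measured with 100 circular shifts of 3 of the 4 lists along each chromosome. Neighbouring regions were compared with 1000 permutations of the presence patterns within chromosomes.

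The rule for naming regions was set before the data were examined. It took, for each population, the 3 windows of 100 kb on a fixed grid with the most own regions and the widest own region, together with the 3 windows with the most regions held by all 4 lists. The parts of the rule that name genes could not be applied. Alternatives set at the same time were a reciprocal overlap of 50% in place of 1 bp, merging of peaks up to 500 bp apart, random thinning of each list to 45461 peaks (the shortest list, mean of 20 draws), the widest 22730 peaks of each list, autosomes only, and peaks of at least 200 bp. A limit of 500 bp on merged regions was added after seeing the data. The merging, overlap and neighbour functions were tested on simulated data. In 82365 simulated regions, 100% received the right presence pattern, and 200 regions switched from all lists to High alone were found as 200 additional High regions. Each simulated peak kept most of the width of 1 merged region. The simulation therefore checked the code, and not how slight overlaps or several peaks of a list in a region are handled. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.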

Results

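Chromatin accessibility was compared between 4 populations of mouse intestinal epithelial cells, sorted by the level of an EGFP reporter of Sox9, a transcription factor of the intestinal crypt. In earlier work with this reporter mouse, Low cells were enriched for crypt base stem cells, Sublow cells for transit-amplifying progenitors, High cells for enteroendocrine and related secretory cells, and Negative cells for differentiated cells. For each population, 3 Omni-ATAC-seq libraries were represented by 1 consensus list of open regions (peaks) on mm9, so the values below have no replicate error and no test across replicates could be made.

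The Low list held the most open regions and the Negative list the fewest. There were 58356 peaks in Low, 54395 in High, 52113 in Sublow and 45461 in Negative. They covered 30.1 Mb in Low, 28.7 Mb in Sublow, 25.9 Mb in High and 21.5 Mb in Negative. Sublow peaks were the widest, with a median of 464 bp, against 433 bp in Low, 394 bp in Negative and 383 bp in High. The same order of Sublow and Low over the other two was seen within regions that all 4 lists held. In the 25643 of these with 1 peak per list, the median peak width was 658 bp in Sublow (bootstrap 95% interval 652 to 663), 643 bp in Low (637 to 648), 565 bp in High (558 to 572) and 529 bp in Negative (523 to 535). The lists give no read depth, so the part that library depth has in peak number and width is unknown.

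To find which open regions the populations had in common, the 4 lists were merged into 82365 regions. A core of 27294 regions, 33.1% of the total (exact 95% interval 32.8 to 33.5%, bootstrap 32.4 to 33.9%), was open in every population. These regions made up 61.5% of the Negative regions, 52.7% of the Sublow regions, 50.9% of the High regions and 47.5% of the Low regions. They were wide, with a median of 743 bp (bootstrap interval 738 to 749), and 80.4% of them reached 500 bp. Another 26293 regions (31.9%) were held by 1 list alone and had a median width of 220 bp, and 5.17% of them reached 500 bp. A merged region spans the peaks of every list that holds it, so its width grows in part with the number of lists. When the lists were shifted along the chromosomes, 0.00116% of regions fell in all 4 lists on average and at most 0.00344% in any of 100 shifts. The share in all 4 lists was 24.8% with a reciprocal overlap of 50% and 19.97% after random thinning of the lists to equal size, which itself takes peaks from shared regions.

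**Figure D1:**
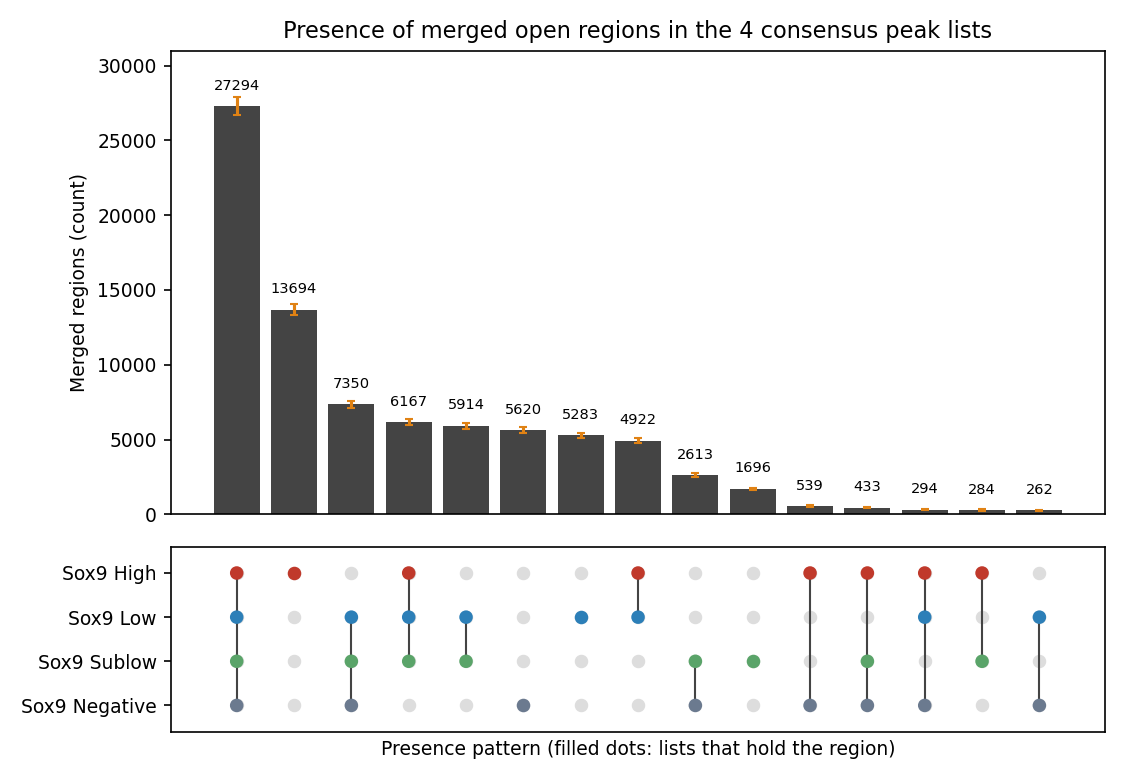
Number of merged open regions (vertical axis, count) for each of the 15 presence patterns, with filled dots marking the lists that hold the region and orange bars the 95% block bootstrap interval. Regions of all 4 lists (27294) come first, High alone second (13694), and the 5 rarest patterns, from 539 to 262 regions, are those that skip a neighbouring reporter level.

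The list of the population with the highest reporter level had the most regions of its own. The High list alone held 13694 regions, which was 25.5% of all High regions (bootstrap 24.8 to 26.2%). Negative had 5620 own regions (12.7%, 12.3 to 13.1%), Low had 5283 (9.19%, 8.86 to 9.48%) and Sublow had 1696 (3.28%, 3.13 to 3.42%). High thus had 2.44 times as many own regions as Negative (bootstrap 2.33 to 2.55), 2.59 times as many as Low (2.495 to 2.709) and 8.07 times as many as Sublow (7.63 to 8.55), intervals that exclude equal numbers. Negative and Low were close in the deposited lists, at a ratio of 1.06 (1.01 to 1.12), but not with the widest peaks only, where High had 4679 own regions, 1.29 times the 3624 of Negative, and Low had 1495. Own regions of High were also wider, with a median of 245 bp (242 to 248) against 205 bp in Low (202 to 209), 201 bp in Negative (199 to 204) and 184.5 bp in Sublow (182 to 188). Among regions of at least 500 bp, High had 1038 own regions, Negative 156, Low 134 and Sublow 31.

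The own regions of High lay farther from regions of other lists than did the own regions of Low, Negative and Sublow. Their median distance to the nearest region that another list held was 8532 bp (bootstrap 8091 to 9034), against 5305 bp for Low (5006 to 5586), 3498 bp for Negative (3308 to 3696) and 2930 bp for Sublow (2635 to 3327). Within 1000 bp of such a region lay 9.95% of the High own regions, 16.4% of those of Low, 19.2% of those of Negative and 26.2% of those of Sublow. No chance distance was computed, so these values only rank the lists. The regions measured against also differ by list, since those for Low, Negative and Sublow include the many own regions of High. High had the most own regions and Sublow the fewest under each of the 6 alternatives that gave these counts. The lead of High over the next list was smaller in some: 1.94-fold after thinning to equal size, 1.92-fold with a reciprocal overlap of 50%, and 1.29-fold with the widest peaks only. The counts themselves moved by over 1.5 times under several alternatives, among them Negative at 9432 own regions with a reciprocal overlap of 50%.

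Regions missing from 1 population were missing mostly from an end of the reporter range. There were 7350 regions that Negative, Sublow and Low shared and High lacked, and 6167 that Sublow, Low and High shared and Negative lacked. Only 433 regions were missing from Low alone and 294 from Sublow alone. The regions missing from High alone were 17.0 times as many as those missing from Low alone (bootstrap 15.4 to 18.8) and 25 times as many as those missing from Sublow alone (22.5 to 28.2). The regions missing from Negative alone were 14.2 times as many as those missing from Low alone (12.96 to 15.73). Regions missing from High alone outnumbered those missing from Negative alone 1.19-fold (1.14 to 1.25). In the regions of all 4 lists with 1 peak per list, Negative and High also had the narrowest peaks. Their medians were 529 and 565 bp, against 658 bp in Sublow and 643 bp in Low. Lower sensitivity of the end lists was not modelled and stays open, and the intervals do not cover it. The regions missing from High alone or Negative alone also count toward the reporter order share given next, so these results are not separate.

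Sharing followed the reporter level. Of the 28778 regions held by 2 or 3 lists, 26966 were held by populations that are neighbours in the order Negative, Sublow, Low, High, a share of 93.7% (exact 95% interval 93.4 to 94.0%, bootstrap 93.4 to 94.0%). The pairs in that order were Sublow with Low at 5914 regions, Low with High at 4922 and Negative with Sublow at 2613. The pairs that skipped a level were rare, with 539 regions for Negative with High, 284 for Sublow with High and 262 for Negative with Low. Among the 12 possible orders of the 4 names the reporter order ranked first, and the next, Negative, Low, Sublow, High, placed 69.4% of these regions side by side. With only 12 orders the rank is no test at the usual threshold and is given as a description. Shifted lists gave 52.9% on average and at most 55.3%. Such lists meet only by chance and nearly always in pairs, so this value is no background for the share among related lists. After random thinning the share was 69.2%, close to the 65.2% of the next order, Low, Sublow, Negative, High.

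The 6 pairs of lists fell into a graded series of overlap. Sublow and Low were the nearest, with a Jaccard index over bases of 0.743 (bootstrap 0.740 to 0.747), and 90.2% of Sublow peaks overlapped a Low peak. Negative and Sublow followed at 0.612 (0.607 to 0.616), then Low and High at 0.541 (0.534 to 0.548), Negative and Low at 0.522 (0.516 to 0.528), Sublow and High at 0.504 (0.496 to 0.511) and Negative and High at 0.441 (0.434 to 0.449). The bootstrap interval of the difference excluded 0 for each of the 15 comparisons between pairs, the smallest being Negative and Low over Sublow and High by 0.0177 (0.0137 to 0.0219). Shifted lists gave mean indices from 0.00495 to 0.00615. After thinning to equal size, Negative and Sublow (0.555) passed Sublow and Low (0.542), and both Negative and Low (0.442) and Sublow and High (0.3999) passed Low and High (0.397). In that setting the Negative list stays whole while the others lose peaks at random. With the widest peaks only, Sublow and High (0.552) passed Negative and Low (0.549).

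**Figure D2:**
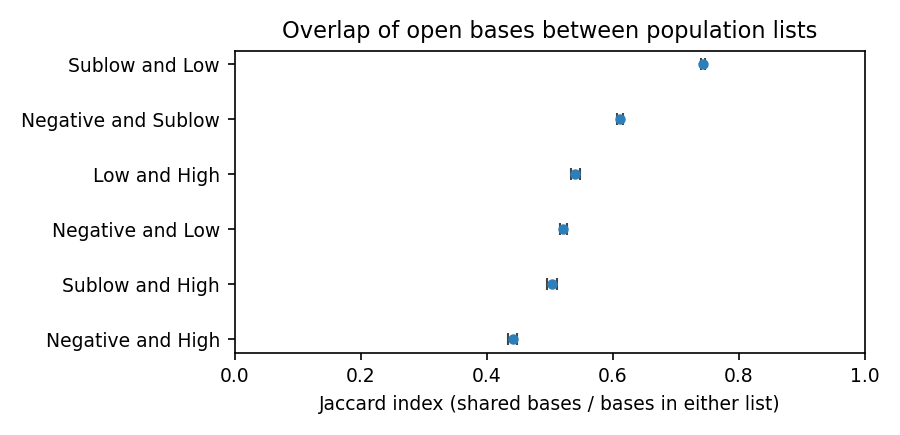
Jaccard index over bases (horizontal axis, from 0 to 1) for the 6 pairs of population lists, with points for the deposited lists and bars for the 95% block bootstrap interval. Overlap runs from 0.743 for Sublow and Low down to 0.441 for Negative and High.

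Between neighbouring reporter levels, each list of the pair held regions that the other lacked. Between Low and Sublow, 46725 regions were held by both, 10761 by Low only and 5026 by Sublow only. Between Sublow and Negative, 37690 were held by both, 14061 by Sublow only and 6715 by Negative only. Between Low and High, 38677 were held by both, 18809 by Low only and 14950 by High only. Presence in a list is a threshold on signal that the lists do not give, so these counts do not measure how far accessibility differed at a region.

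The windows of the genome with the most own regions differed in number of own regions between the populations, and no chance value was computed for them. For High, the 100 kb window with the most own regions was chromosome 18 from 82700001 to 82800000, where 10 of 15 regions were held by High alone, with a median width of 221 bp. Next came chromosome 6 from 54000001 to 54100000 with 10 of 19, and chromosome 10 from 117300001 to 117400000 with 9 of 11, where Negative and Sublow held 1 region each. For Negative, chromosome 19 led with 8 of 13 regions from 32100001 to 32200000 and 8 of 15 from 57400001 to 57500000, followed by chromosome 7 with 7 of 18 from 139900001 to 140000000. For Low, 5 of 8 regions were its own on chromosome 3 from 148800001 to 148900000 and 5 of 8 on chromosome 11 from 117300001 to 117400000, where Negative held no region. A window on chromosome 1 from 191600001 to 191700000 had 5 of 11. For Sublow the highest numbers were 4 of 10 regions on chromosome 17 from 28700001 to 28800000, 4 of 20 from 24100001 to 24200000 on that chromosome, and 3 of 8 on chromosome 8 from 114400001 to 114500000. The genes in these windows were not analysed here.

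**Figure D3:**
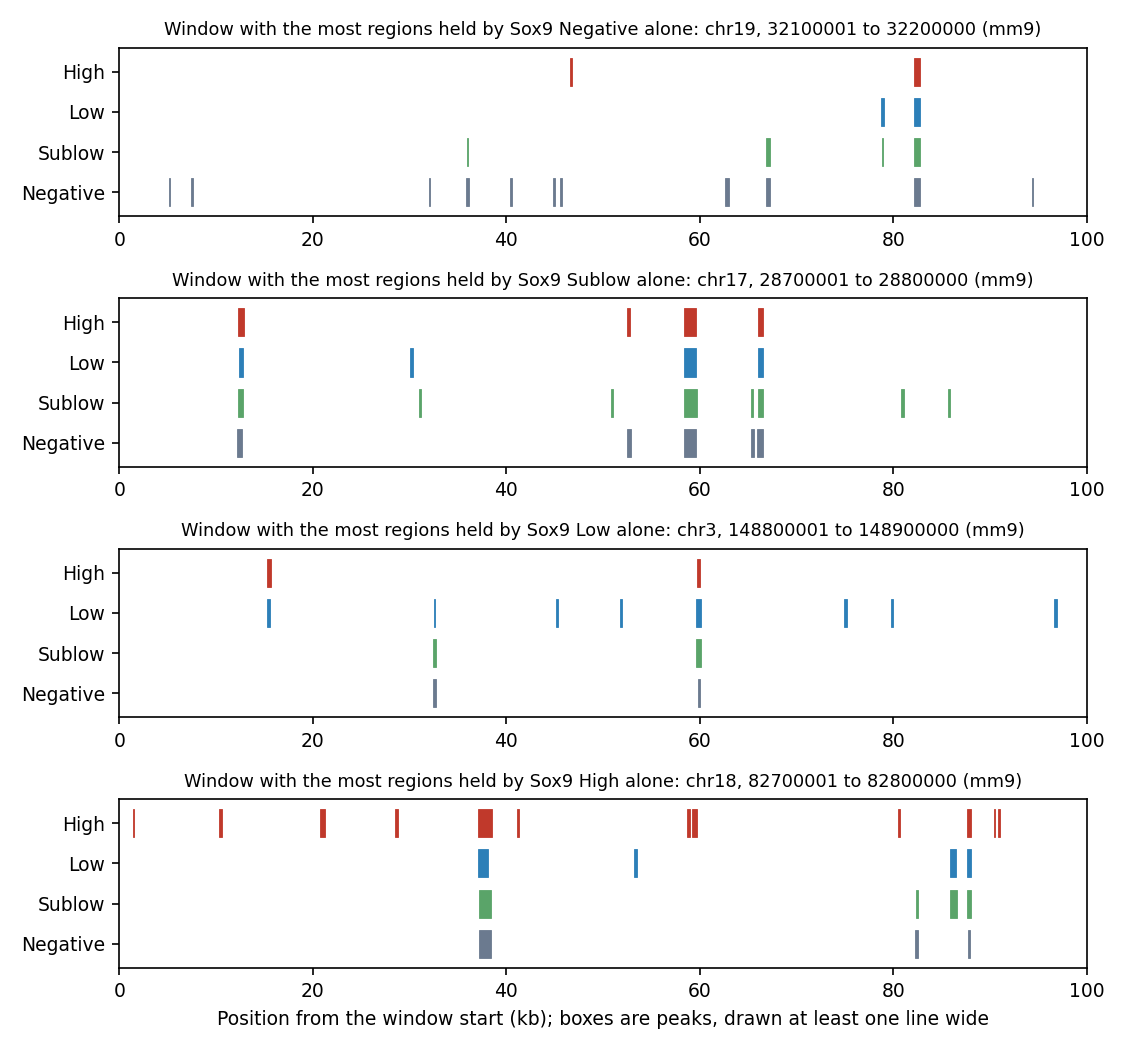
Peaks of the 4 lists (rows) along the 100 kb window with the most own regions of each population, with position in kb from the window start on the horizontal axis and boxes for peaks. The chromosome 18 window has 12 High regions and 3 Negative regions, and the chromosome 19 window 11 Negative regions and 2 High regions.

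The windows with the most regions of all 4 lists were chromosome 10 from 79600001 to 79700000 (15 of 19 regions), chromosome 3 from 89000001 to 89100000 (15 of 20) and chromosome 7 from 30000001 to 30100000 (15 of 23). The widest own region of High covered 1742 bp on chromosome 11 from 80965490 to 80967231, and that of Negative 1642 bp on chromosome 19 from 43867170 to 43868811. The widest own region of Low covered 944 bp on chromosome 5 from 35621575 to 35622518, and that of Sublow 849 bp on chromosome 7 from 148942360 to 148943208.

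Chromosome 11 was the densest autosome in each list, at 34.5 peaks per Mb in Low, 32.8 in High, 31.0 in Sublow and 28.1 in Negative. The X chromosome was sparse, at 6.96 peaks per Mb in Low, 6.34 in Sublow, 5.81 in High and 5.29 in Negative, against autosome means of 23.1, 20.7, 21.6 and 18.04. Each list also held a few Y peaks (17 in Negative, 16 in Sublow, 17 in Low and 14 in High). Densities were not corrected for the copy number of X, so its sparseness cannot be read as a property of its chromatin. The X chromosome held 2.03% of Sublow peaks (exact 95% interval 1.91 to 2.15%), 1.98% of Low peaks (1.873 to 2.101%), 1.94% of Negative peaks (1.81 to 2.07%) and 1.78% of High peaks (1.67 to 1.89%). The intervals of Sublow and High did not overlap, but exact intervals treat peaks as independent. No bootstrap interval was computed for these shares, so a difference between the populations was not shown. On each of the 19 autosomes High had the most own regions, from 13.7% to 18.6% of the merged regions of the chromosome.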

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

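No paired analysis was possible because each population is given as 1 consensus list with no value per library, and for the same reason no replicate could be left out. The alternatives for gene lists, position in genes and motifs were not run, since an mm9 genome or annotation was not used here. High had the most own regions, Sublow the fewest, and the reporter order ranked first under the 6 alternatives that gave these values, including the limit of 500 bp, which was chosen after seeing the data. Peak numbers, shares on the X chromosome, and the results on autosomes only stayed within 1.5-fold or inside their intervals, also with peaks of at least 200 bp where that was run. With a reciprocal overlap of 50%, the share in all 4 lists was 24.8%, own regions numbered 9432 in Negative, 3962 in Sublow and 8621 in Low, the reporter order share was 91.0%, and the Jaccard indices were 0.565 (Negative and Sublow), 0.478 (Negative and Low), 0.404 (Negative and High), 0.717 (Sublow and Low), 0.465 (Sublow and High) and 0.501 (Low and High). Merging peaks up to 500 bp apart gave a share in all 4 lists of 34.4%. Thinning to equal size gave 19.97% in all 4 lists, 2890 own regions in Sublow, a reporter order share of 69.2%, and Jaccard indices, in the same order of pairs, of 0.555, 0.442, 0.391, 0.542, 0.3999 and 0.397. Random thinning drops a shared peak from one list and not from another, so lower overlap follows from its construction. With the widest peaks only, 40.0% of regions were in all 4 lists, own regions numbered 3624 in Negative, 860 in Sublow, 1495 in Low and 4679 in High, the reporter order share was 83.8%, and the indices were 0.549 (Negative and Low), 0.490 (Negative and High), 0.752 (Sublow and Low), 0.552 (Sublow and High) and 0.576 (Low and High). These lists hold fewer peaks by construction. Regions of at least 500 bp were in all 4 lists for 68.2%, with 156 own regions in Negative, 31 in Sublow, 134 in Low and 1038 in High, and a reporter order share of 96.8%. In all, 38 values moved past these limits and 40 did not. Depth is unknown, so whether a region missing from a list was closed or missed cannot be told from the lists.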

Other observations

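The test of nested lists was chosen after the presence patterns were seen, as were the control added to the mixture tests and the comparison at matched widths after the first values of those tests, and the permutation among regions of like spacing after the first neighbour ratios. Relative to regions of all 4 lists, peaks were narrower next to the population that lacked a region. In 7165 regions with 1 peak each in Negative, Sublow and Low and none in High, median peak widths were 319 bp in Negative, 399 bp in Sublow and 344 bp in Low, and the median log2 ratio of Low to Negative width was 0.08, against 0.22 in regions of all 4 lists. The difference of -0.14 had a bootstrap interval from -0.16 to -0.12, and it was -0.18 (-0.20 to -0.16) against regions of all 4 lists drawn to the same widths. In 5998 regions with 1 peak each in Sublow, Low and High and none in Negative, the log2 ratio of Sublow to High width was -0.06, against 0.13 in regions of all 4 lists, a difference of -0.19 (-0.21 to -0.17), or -0.24 (-0.27 to -0.22) at matched widths. A hypothesis is that accessibility at these regions changes by degrees along the reporter range and not in 1 step, and both values are consistent with it. A sort in which neighbouring populations share cells would give the same pattern.

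A pattern a reader might follow up is the large number of own regions of High. The list length was argued against, since after thinning to equal size High still had 1.94 times (1.937) as many as the next list and the longer Low list had fewer. Weak peaks near the calling limit were argued against only for regions of at least 500 bp, where the ratio was 6.65. These were 1038 of the 13694 own regions of High (7.58%). With the widest peaks of each list the ratio was 1.29, and width only stands in for strength. Weak peaks therefore stay open for the narrower own regions, which are most of them. Concentration in a few chromosomes was argued against, since High led on 19 of 19 autosomes. Unequal depth, unequal agreement of the libraries behind each consensus list, and a biological difference between High cells and the others stay open, because the lists hold no value per library.

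The second pattern is that regions of 2 or 3 lists followed the reporter order. The best nested order of lists that differ only in sensitivity (Sublow, Low, Negative, High) covered 46.1% of these regions, a value that is not comparable with the 93.7% of the reporter order, which admits more patterns. Strict nesting is argued against by the counts themselves, since it allows regions missing from High alone (7350) or from Negative alone (6167) but not both, while unequal sensitivity with chance losses was not modelled and stays open. For Low or Sublow as only a mixture of its neighbours' cells, the share of regions of at least 500 bp in neither neighbouring list was 0.478% in Low and 0.228% in Sublow. Both are under the bound of 1% set for a mixture before this test. Merged regions of more lists are wider, so the limit of 500 bp itself lowers these shares. Over all widths, 9.19% of Low regions and 3.28% of Sublow regions were held by no other list. Those values are over 1%, so being under the bound depends on the limit of 500 bp, which was chosen after seeing the data. Of the end lists, which lie between no others, High was over the bound (3.81% of regions of at least 500 bp in no other list) and Negative under it (0.607%). A value under the bound therefore does not single out a mixture, and sorting spill-over and a series of states cannot be told apart here.

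The third pattern is that own regions of a population tended to be next to each other. High had 3797 pairs of successive own regions, 1.66 times the mean of 1000 permutations of the patterns within chromosomes (permutation p = 0.001, the smallest they can give), and the ratio was 1.68 for Negative, 1.54 for Low, 1.39 for Sublow (permutation p = 0.022) and 1.13 for regions of all 4 lists. For neighbours over 5 kb apart the ratio was 1.95 for High, which argued against one broad open region split into several peaks as the whole cause there. It was 1.53 for Low, 1.34 for Negative and 1.11 for Sublow (permutation p = 0.328), so splitting stays open for Sublow. A sparser placement of own regions was argued against as the whole cause for High, since its ratio was 1.56 when patterns were permuted among regions of like spacing. That permutation was run at any distance and not with the limit of 5 kb, which itself favours sparsely placed regions. Splitting and sparse placement acting together therefore stay open for High. A candidate explanation is that own regions cluster around loci used in that population, and this was not tested, since genes were not assigned.

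The widest region of all 4 lists covered 5622 bp on chromosome 17 from 39980065 to 39985686 and lay 239399 bp from the next region. No filter for repeated sequence or mapping artifacts was applied here, and what lies in this region was not analysed. Peaks under 100 bp made up 0.825% of the High list, 0.658% of Negative, 0.476% of Low and 0.418% of Sublow.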
